A study of Mus musculus with 18 samples.

How the data were processed

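Thymocytes were collected from wild-type mouse thymi that had been grafted for 28 days, per the labels' protocols. DN3 cells, the CD4 and CD8 double-negative stage at which T-cell receptor beta genes rearrange, and DP cells, the later stage that carries both CD4 and CD8, were sorted by flow cytometry into lysis buffer. RNA was pulled away from genomic DNA on oligo-dT beads and libraries were made with the Pico Nextera protocol, per the labels' protocols. Per the labels, 18 libraries fall into 4 groups: DN3 turnover and DP turnover with 4 libraries each, and DN3 autonomy and DP autonomy with 5 libraries each. In work on thymus grafts, turnover means that thymocytes are replaced by progenitors entering from outside, and autonomy that the graft keeps itself without them. The hosts, the strains and the sex of the animals are not given in the sources used here, and the labels do not say that libraries of one group come from separate animals, so p-values measure the spread between these samples.

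The deposited count table holds raw whole-number read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, FastQC, HISAT2, featureCounts and DESeq2 were used on the mouse builds mm10 and GRCm38, with versions and settings not given in the sources used here. The table lists 22619 genes, 17934 of them with at least 1 read in any library, and 22601 of the identifiers matched the GENCODE M21 annotation of GRCm38, which supplied gene symbols where the deposited tables had none, and the coordinates. All 18 count columns were matched to a sample by name. The authors also deposited a DESeq2 table for each cell type, autonomy against turnover, with 22566 genes. In it the log2 fold changes and their standard errors are the authors' own, as are the p-values and adjusted p-values, per the file headers. These tables were used only to compare calls. Whether the counting used strand is not given in the sources used here, so genes that overlap on opposite strands, and near-identical family members such as the H2-Q, H2-T and Ifi200 genes, have uncertain values.

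Total counts ran from 7426834 to 21808512 in the DN3 libraries and from 5032273 to 24191044 in the DP libraries. CPM values, counts scaled to a common library size, were computed here from the deposited counts with TMM factors. No 2 libraries agreed within sampling noise: the lowest Pearson correlation of log2 CPM within a group was 0.913 among DN3 libraries and 0.882 among DP libraries.

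Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest), TMM scaling and the filterByExpr filter, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Autonomy was compared with turnover within DN3 libraries alone and within DP libraries alone. A single model of all 18 libraries with 4 group means gave the difference of the autonomy effect between DP and DN3, and DP against DN3 within each condition. No block was used in these fits. Fold changes against a group with no reads in any library are given as lower bounds against a floor of 3 counts per library. Such floors cover counting error only, since amplified reads are not independent molecules.

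The text names genes by a rule: per cell type, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups; up to 2 members per direction of each gene list; 17 thymocyte genes in every case; and the 6 largest differences per direction between the cell types. Predicted genes and T-cell receptor segments were left out of the first part and summarised as classes. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule picks are not reported here, and they remained in the fits and in the lists.

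Gene lists, 35 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, and again with a correlation estimated for each list. They covered Notch targets, pre-TCR and TCR signal-induced genes, S phase, G2 and mitosis, Rag recombination, early progenitor genes, T-lineage identity, double-positive stage genes, positive selection, gamma-delta lineage genes, the IL-7 receptor pathway, p53 targets, the Bcl2 family, T-cell leukaemia genes, Myc targets in ribosome biogenesis, interferon-stimulated genes, immediate early and heat shock genes, glucocorticoid-responsive genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein and integrated stress response, histones, ribosomal proteins and mitochondrially encoded genes. Markers of other cells covered B cells, macrophages, dendritic cells, NK cells, thymic epithelium, fibroblasts and endothelium, erythroid cells and platelets, kidney tubule, mast cells and granulocytes, and sex-linked genes. The sample groups, tests, lists, naming rule and the other settings tried were fixed before the data were examined, apart from those marked as chosen after the data or a result were seen.

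The fits were tested on simulated counts drawn from the real library sizes and from the mean of each gene over all libraries of the fit, with 200 genes changed. The changed genes were picked among those with a mean of at least 10 CPM, so the shares below do not hold for genes with lower means. At a 2-fold change, 62% of the changed genes were recovered in the DN3 comparison and 41% in the DP comparison, and at a 4-fold change 97% and 83%. For the difference between cell types the recovered shares were 11% at 2-fold and 72% at 4-fold. DP against DN3 recovered 37% and 90% in turnover, and 41% and 90% in autonomy.

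The other settings tried were other scalings (RLE, upper-quartile, and scaling without mitochondrial and ribosomal protein genes), 2 other filters on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, robust dispersion, a threshold of 0.01, a test against a 1.5-fold change, a fit of all 18 libraries, libraries that share a number and differ in the letter A or B summed to 1, the rotation test fry for the lists, the sample identifier as a block, and leaving out each library in turn. Libraries of both cell types carry the same identifier in 8 cases.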

Results

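Gene expression was measured by RNA sequencing in sorted DN3 and DP thymocytes from grafted mouse thymi, with 18 libraries in 4 groups. The DN3 turnover group held 4 libraries with total counts of 12260295 to 14846126, and the DN3 autonomy group held 5 libraries with 7426834 to 21808512. The DP turnover group held 4 libraries with 6329039 to 24191044, and the DP autonomy group 5 libraries with 5032273 to 20076446. Cell type was the main axis of variation: the first principal component of all 18 libraries carried 43.5% of the variance and separated DN3 from DP. Mitochondrial transcripts took 3.46% to 5.55% of the DN3 counts and 2.69% to 3.78% of the DP counts. Below, a level is a mean ± SD in CPM, counts scaled to a common library size, over 4 turnover or 5 autonomy libraries, and a log2 change, autonomy over turnover unless stated, carries its standard error (SE) from the edgeR fit.

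The first comparison asked how DN3 cells differ when the graft keeps itself without new progenitors. In autonomy, Ccr9, the chemokine receptor that guides progenitors and thymocytes towards thymic stroma, fell 26.7-fold, from 264 ± 108 to 10.1 ± 8.22 CPM (log2 −4.74, SE 0.52, adjusted p = 0.000234). The gene, ENSMUSG00000029530, lies on chromosome 9 of GRCm38 from 123678439 to 123784330. Kit, the stem cell factor receptor of early progenitors, fell from 51.4 ± 18.7 to 10.4 ± 7.76 CPM, and Bcl2, which protects from apoptosis, from 96.5 ± 15.0 to 43.5 ± 5.75 CPM. Gpr83, a G-protein-coupled receptor, rose 91.1-fold, from 0.921 ± 0.83 to 84.7 ± 36.3 CPM (log2 6.51, SE 0.64, adjusted p = 0.000131). In all, 1602 of 10766 genes passed the edgeR quasi-likelihood test, 703 higher and 899 lower in autonomy, with 171 and 609 of them changed at least 2-fold. Turnover libraries RP1140A and RP1140B share a number, as do RP1141A and RP1141B, and the labels do not say whether they are separate animals; with A and B summed 507 genes passed, 499 of them among the 1602. In a fit of all 18 libraries 1006 passed, and 2869 with voom. The groups did not overlap for 1982 genes, or 18.4%, where chance gives 1.59% if all 9 libraries are separate samples, and more if they are not. Without turnover library RP1140A 811 genes passed, without autonomy library RP1137 953, and without autonomy library RP1138 1060.

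Among the largest DN3 rises, Adam19, a metalloprotease, had no reads in turnover and 20.8 ± 9.43 CPM in autonomy, at least 97.4-fold higher. Pdlim4, a PDZ and LIM domain protein, rose 57.9-fold, and Id1, an inhibitor of DNA binding by E proteins, 50.6-fold, from 0.352 ± 0.41 to 17.9 ± 11.8 CPM. Arsi, of the arylsulfatase family, rose 16.6-fold (log2 4.05, SE 0.36, adjusted p = 7.94e-05). Necab1, Exoc3l4 and Fstl4 rose by log2 4.71, 4.12 and 3.91. Hoxa7, a homeobox transcription factor, fell 84.7-fold, from 19.98 ± 12.3 to 0.222 ± 0.33 CPM. Scin, an actin-severing protein, fell 22.9-fold, Tifa, a TRAF-binding adaptor, 16.2-fold, and Atp8b4, of the phospholipid-transporting ATPase family, 12.2-fold. Ica1, Rab38, Zcchc12, Rbm44 and Rec8 had log2 changes of −4.21, −4.20, −4.12, −4.18 and −3.51. Close paralogs filled the remaining places, with uncertain values because reads can be shared between them: Ifi211 (log2 5.06), Ifi204 (4.35), H2-T3 (4.22) and H2-Q1 (4.14) were higher, H2-Q6 (−4.61) and H2-Q7 (−3.92) lower. Of these 24 genes, 22 kept the call without each library in turn; without turnover library RP1140A Rbm44 had adjusted p = 0.0516 and H2-Q7 0.0614. Some sizes moved by over 1.5-fold with 1 library left out, all to a larger change but for H2-T3. Without turnover library RP1141B Id1 was at log2 6.72 and H2-Q1 at 5.22. Without RP1140B Necab1 was at 5.34 and Exoc3l4 at 4.87, and without RP1140A H2-T3 was at 5.51. Without autonomy library RP1133 Hoxa7 was at −7.66 and Rbm44 at −8.39. Without RP1135 H2-Q6 was at −6.66, H2-Q7 at −4.95 and Atp8b4 at −4.85. Without RP1138 Rec8 was at −4.34, and without RP1134 H2-T3 was at 3.29.

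Cell-cycle genes were higher in DN3 autonomy. Of 28 S-phase and DNA replication genes, 24 rose, 0 fell and 4 did not pass, and adjusted over the list alone 26 rose (camera adjusted p = 5.02e-14, and adjusted p = 0.302 with an estimated correlation). Ccne1 and Ccne2, the E-type cyclins of S-phase entry, rose by log2 1.43 (SE 0.26) and 1.29 (SE 0.20). Of 29 G2 and mitosis genes, 20 rose, 0 fell and 9 did not pass, and adjusted over the list alone 25 rose (camera adjusted p = 5.54e-13, and adjusted p = 0.302 with an estimated correlation). Hmmr, which binds the spindle, rose from 91.3 to 220 CPM (log2 1.27, SE 0.15) and Anln, a cytokinesis protein, by log2 1.17 (SE 0.22). Mki67, a proliferation marker, rose from 295 to 535 CPM (log2 0.86, SE 0.24, adjusted p = 0.0303); it lost the call without turnover library RP1140A (0.074), RP1141B (0.0678) or autonomy library RP1138 (0.0526). Of 21 histone genes 2 rose and 19 did not pass, and adjusted over the list alone 1 rose (camera adjusted p = 0.00138, and adjusted p = 0.48 with an estimated correlation), among them H2afz (log2 0.93, SE 0.15). Turnover library RP1141B, which carried transcripts of DP genes as given below, is part of this comparison; without it 23 S-phase and 16 G2 genes rose.

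The lists of Myc targets, stress response, oxidative phosphorylation and ribosomal proteins passed camera in DN3 autonomy, and each lost the call with an estimated correlation. Of 26 Myc targets in ribosome biogenesis 8 rose and 18 did not pass, and adjusted over the list alone 14 rose and 1 fell (camera adjusted p = 5.93e-06, and adjusted p = 0.48 with an estimated correlation); without turnover library RP1140A, RP1140B or RP1141B 1, 2 and 3 rose, and without autonomy library RP1133, RP1137 or RP1138 5, 1 and 1. Nolc1, a nucleolar assembly factor, rose from 222 to 415 CPM. Of 18 genes of the unfolded protein and integrated stress response 6 rose and 12 did not pass, and adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.00258, and adjusted p = 0.347 with an estimated correlation); Mthfd2, a mitochondrial folate enzyme, rose by log2 1.08 (SE 0.16). Without turnover library RP1140A 2 of these rose. Of 35 oxidative phosphorylation genes 3 rose, Uqcrfs1 among them (log2 0.81, SE 0.13), and 32 did not pass; adjusted over the list alone 1 rose (camera adjusted p = 5.93e-06, and adjusted p = 0.544 with an estimated correlation). Without turnover library RP1140A or RP1140B or autonomy library RP1133, RP1137 or RP1138 1 of these rose, and without RP1135 5. Of 60 cytosolic ribosomal protein genes 2 rose and 58 did not pass, and adjusted over the list alone 0 passed (camera adjusted p = 0.00138, and adjusted p = 0.67 with an estimated correlation); without turnover library RP1141B camera gave adjusted p = 0.305, and without RP1141A 4 rose.

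Some genes of the earliest thymic stages fell in DN3 autonomy. Of 13 early progenitor genes 0 rose, 3 fell and 10 did not pass, with 4 falling adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.404 with an estimated correlation). Kit fell by log2 −2.31 (SE 0.48), Cpa3, a protease of mast cells and early progenitors, from 89.1 to 12.7 CPM (log2 −2.82, SE 0.58), and Nfe2, a transcription factor, from 28.7 to 5.04 CPM; without autonomy library RP1135 7 of the list fell, with Nfe2 at log2 −3.53. Of 15 gamma-delta lineage genes 1 rose, 6 fell and 8 did not pass, with 1 rising and 8 falling adjusted over the list alone (camera adjusted p = 0.0499, and adjusted p = 0.347 with an estimated correlation); 5830411N06Rik fell from 98.6 to 8.78 CPM and Blk, a Src family kinase, by log2 −1.64 (SE 0.26). That list call was lost without turnover library RP1140B (0.0831) or RP1141B (0.0926), or autonomy library RP1134 (0.0645) or RP1135 (0.0721). Markers of other cells moved with this group: Cpa3, the mast cell gene tested, fell, as did Lyz2 of macrophages (log2 −2.65, SE 0.53), H2-Ab1 of dendritic cells (−1.96, SE 0.44), Cd79b of B cells (−1.48) and Nkg7 of NK cells (−2.93, SE 0.68). Without autonomy library RP1135 Lyz2 was at −3.48 and Nkg7 at −4.34. Of the other 6 NK markers 3 rose, Id2 among them (log2 1.20), and 0 fell.

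T-lineage genes moved in both directions in DN3 autonomy, and the lists given in this paragraph did not pass camera. Dntt, the enzyme that adds nucleotides at receptor gene joints, fell from 3529 ± 358 to 1817 ± 400 CPM (log2 −0.96, SE 0.17, adjusted p = 0.00367), and Bcl11b, the T-lineage commitment factor, by log2 −1.05 (SE 0.19). Of 25 T-lineage identity genes 2 rose and 5 fell, and adjusted over the list alone 3 rose and 8 fell (camera adjusted p = 0.121); Lef1, a partner of beta-catenin, rose by log2 0.76 (SE 0.15), while Lat2, an adaptor, and Myb, a progenitor transcription factor, fell by 3.23 and 1.13 on the log2 scale, and Lat2 by 4.22 without autonomy library RP1135. Of 15 Rag recombination genes 2 rose and 2 fell, and adjusted over the list alone 6 rose and 2 fell (0.302), with Hmgb2 at log2 0.98 and Rag1 at −0.11. Of 12 Notch genes 4 rose and 1 fell, and adjusted over the list alone 5 rose and 2 fell (0.302); they included Gpr83 (log2 6.51), with Notch1 at log2 0.27 (SE 0.28, adjusted p = 0.539). Of 15 pre-TCR and TCR signal-induced genes 2 rose and 3 fell, and adjusted over the list alone 4 rose and 3 fell (0.858); Cd2, an adhesion receptor, rose from 27.5 to 228 CPM (log2 3.06, and 4.63 without turnover library RP1141B). Of 17 IL-7 receptor pathway genes 2 rose and 5 fell, and adjusted over the list alone 2 rose and 6 fell (0.249), with Socs2 at log2 1.69 and Bcl2 at −1.15; Il7r itself was at log2 −0.07. Ptcra (log2 0.64, adjusted p = 0.0521), Il2ra (−0.10), Cd3e (−0.35), Myc (−0.45) and Tcf7 (−0.24) did not pass.

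Of 18 double-positive stage genes 0 rose and 5 fell in DN3 autonomy, the same counts adjusted over the list alone (camera adjusted p = 0.121), and of 21 positive selection genes 2 rose and 10 fell, with 4 and 12 adjusted over the list alone (0.0504). Cd1d1, which presents lipids, fell by log2 −1.2 (SE 0.20) and Cd52, a surface glycoprotein, by −2.86. Turnover library RP1141B held 135 CPM of Cd4 and 385 of Cd8a, against means of 1.19 and 5.59 in the other 3 turnover libraries. With it Cd4 had log2 −3.21 (SE 1.26, adjusted p = 0.101) and Cd8a −0.80 (SE 1.05, 0.637); without it Cd4 was at 1.65 (SE 0.73, 0.149) and Cd8a at 3.37 (SE 0.38, 0.000684), Cd52 at −1.41, while Cd8b1, chosen after its values were seen, was higher in autonomy (2.63, adjusted p = 0.00201). Without RP1141B 3 double-positive stage genes rose and 4 fell (camera adjusted p = 0.729), 1 positive selection gene rose and 9 fell (0.0968), Ccr9 kept its fall (log2 −4.51, adjusted p = 0.000775), and 1408 genes passed in all, 1216 of them among the 1602. Leaving out turnover library RP1141A gave the double-positive list camera adjusted p = 0.0426. The positive selection list passed without turnover library RP1140A (0.032) or RP1140B (0.0454), or autonomy library RP1133 (0.0433), RP1134 (0.0412) or RP1137 (0.046).

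**Figure D1:**
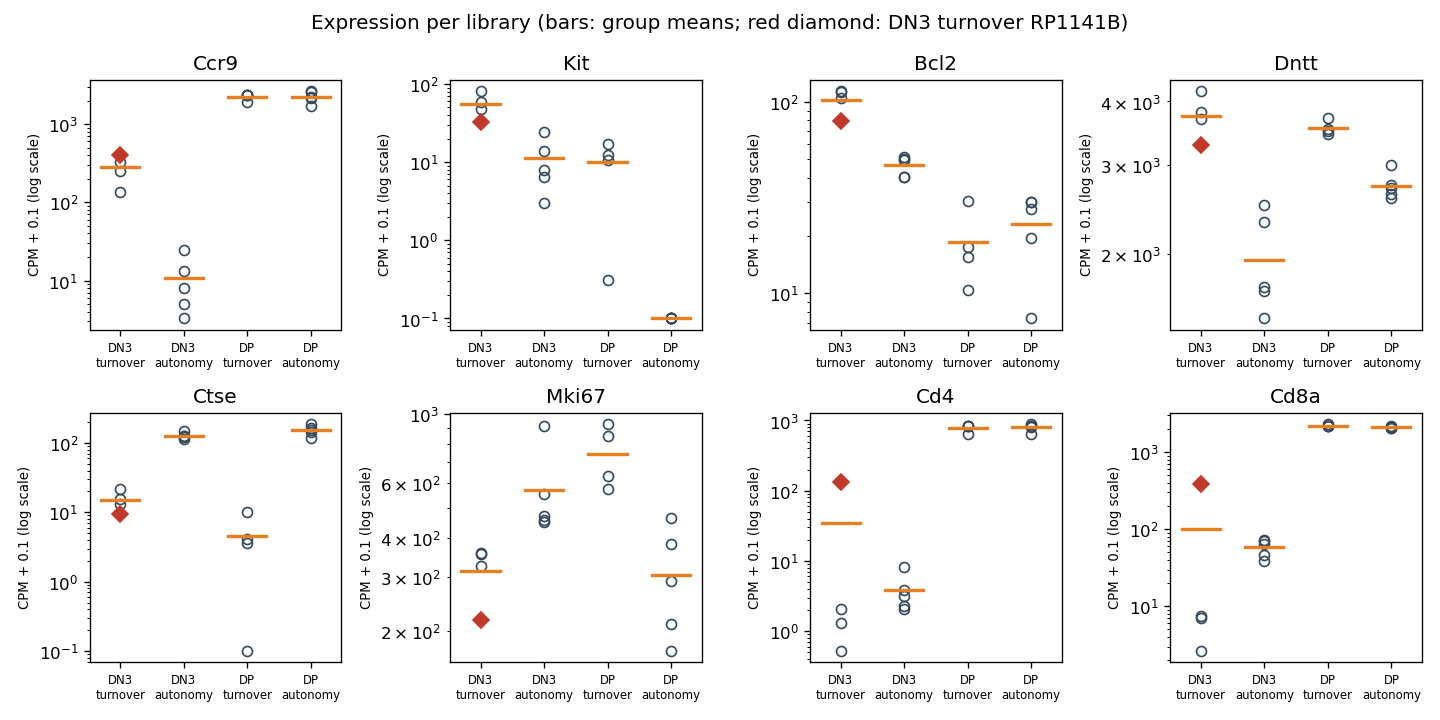
Levels of 8 genes in each of the 18 libraries, in CPM plus 0.1 on a log axis, by group; bars mark group means and the red diamond marks DN3 turnover library RP1141B. Ccr9 averaged 264 CPM in DN3 turnover and 10.1 in DN3 autonomy, and Cd4 was 135 CPM in the marked library.

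The other lists tested in DN3 cells did not pass camera. Of 20 p53 targets 1 rose and 5 fell, and the same adjusted over the list alone (camera adjusted p = 0.68), with Cdkn1a, an inhibitor of the cell cycle, at 61.7 to 20.8 CPM (log2 −1.57, SE 0.25) and Trp53inp1 at log2 −1.78. Of 14 glucocorticoid-responsive genes 0 rose and 5 fell, with 1 rising and 5 falling adjusted over the list alone (0.0602); Pik3ip1, which restrains PI3 kinase, fell from 158 to 27.3 CPM, and Btg2, an antiproliferative gene, by log2 −1.48. The list passed without turnover library RP1141A (0.0433) or autonomy library RP1133 (0.0366) or RP1135 (0.033). Of 22 T-cell leukaemia genes 1 rose and 6 fell, with 1 and 9 adjusted over the list alone (0.121). Of 14 immediate early and heat shock genes 4 rose and 2 fell, with 5 and 2 adjusted over the list alone (0.121); Hsp90aa1 rose by log2 1.04. Of 20 glycolysis genes 3 rose and 2 fell, with 5 and 2 adjusted over the list alone (0.199); Pdk1, which holds back pyruvate use, fell by log2 −1.10. Of 11 Bcl2 family genes 1 rose, the death agonist Bid (log2 1.02), and 1 fell, Bcl2 (−1.15), the same adjusted over the list alone (0.805). Of 21 cholesterol synthesis genes 1 fell, the same adjusted over the list alone (0.986). By edgeR 0 of 32 interferon-stimulated genes (0.986) and 0 of 13 mitochondrially encoded genes (0.774) passed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 and 0, and adjusted 1 and 0 by DESeq2 and 4 and 0 by voom.

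Markers of other cells were few in the DN3 libraries. Of 7 B-cell markers 2 fell (camera adjusted p = 0.253), of 5 macrophage markers 1 (0.506), of 5 dendritic cell markers 2 (0.121) and of 6 thymic epithelial markers 1, Epcam (log2 −1.25; 0.249); adjusted over the list alone the counts were the same. Of 7 NK markers 3 rose and 1 fell, with 3 and 2 adjusted over the list alone (0.761); Id2 rose by log2 1.20 and Nkg7 fell, with log2 −2.93, and −4.34 without autonomy library RP1135. Too few genes were expressed to test the other lists: of 2 fibroblast and endothelial genes 1 fell, Pecam1 (log2 −0.82), while 0 of 1 erythroid gene, Alas2, and 0 of 2 kidney tubule genes passed, and no sex-linked gene was tested in any comparison. The 9 lists that passed camera in DN3 all lost the call with an estimated correlation. The median, mean and test differed in sign for the pre-TCR, Bcl2 family, interferon, cholesterol and NK lists, none of which passed.

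The same question was asked of DP cells. Ctse, the protease cathepsin E, rose 32.9-fold in autonomy, from 4.73 ± 4.43 to 164 ± 26.7 CPM (log2 5.04, SE 0.63, adjusted p = 0.00288; log2 5.78 without turnover library RP1141A). Dtx1, the Notch target, rose 7.96-fold, from 5.33 ± 3.33 to 43 ± 16.2 CPM, and Igf2bp3, an RNA-binding protein of fetal tissues, 3.73-fold. Tmpo, a protein of the nuclear envelope, fell from 482 ± 111 to 149 ± 17.5 CPM (log2 −1.70, SE 0.17, adjusted p = 0.00123). In all, 178 of 10339 genes passed, 89 higher and 89 lower, with 23 and 50 changed at least 2-fold. With A and B libraries summed 16 passed, 15 of them among the 178, while 279 passed in a fit of all 18 libraries, 272 with voom and 736 with DESeq2. The groups did not overlap for 835 genes, or 8.08%, where chance gives 1.59% if all 9 libraries are separate samples, and more if they are not. The DP count rests on few libraries: without turnover library RP1140B 33 genes passed, without RP1141B 59, RP1141A 67, and without autonomy library RP1133 66 or RP1135 98.

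Among the largest DP rises, C1qc, a complement subunit made by macrophages, had no reads in turnover and 13.3 ± 12.2 CPM in autonomy, at least 47.2-fold higher, or 28.2-fold by the same bound without autonomy library RP1133. Wscd1 was at least 36.7-fold higher. The others were mt-Co3, Phlda1, Ckb, Tmsb10, Kbtbd3, Itm2a and Wdr27, between log2 1.46 and 2.67. Without autonomy library RP1136 mt-Co3 was at log2 1.87 and Tbc1d19 at −4.05. The largest falls were Tbc1d19 (log2 −3.25), Arhgap18 (−2.42), Ankrd28 (−1.87, SE 0.27), the nuclear pore gene Nup205 (−1.82, SE 0.25), the cell-cycle inhibitor Rb1 (−1.80, SE 0.27), Sgpp1 (−1.71), the spindle checkpoint gene Bub1b (−1.70, SE 0.22), Vars (−1.65), Ccna2 (−1.64), Ncaph (−1.60) and Anln (−1.55, SE 0.23). Of these 24 genes 10 kept the call without each library, namely C1qc, Ctse, Dtx1, Igf2bp3, Ankrd28, Nup205, Rb1, Bub1b, Tmpo and Anln. The other 14 lost it in at least 1 case, with adjusted p up to 0.131: 13 without turnover library RP1140B, 11 without RP1141B, 10 without RP1141A and 7 without RP1140A, 9 without autonomy library RP1133, 7 each without RP1135 and RP1136, 3 without RP1138 and 2 without RP1137. Of the thymocyte genes always named, Dntt fell from 3799 ± 159 to 2895 ± 185 CPM (log2 −0.39, SE 0.07, adjusted p = 0.0163; 0.0532 without turnover library RP1140B or RP1141B) and Mki67 from 798 to 323 CPM (log2 −1.30, SE 0.26, adjusted p = 0.0293); Mki67 lost the call without turnover library RP1140A, RP1140B or RP1141B or autonomy library RP1133 or RP1136, with adjusted p up to 0.0808 (RP1140B). Notch1 (log2 0.35), Ptcra (0.92, adjusted p = 0.0835), Il2ra (1.92, 0.107), Rag1 (0.11), Cd4 (0.02), Cd8a (−0.09), Cd3e (0.10), Myc (−1.03, 0.0849), Bcl2 (0.30), Bcl11b (−0.31), Tcf7 (−0.19) and Cdkn1a (−1.35) did not pass, nor did Il7r, with no reads in turnover and 2.29 CPM in autonomy (0.0827). Kit, with 673 reads in the 4 turnover libraries, 325 of them in 1 library, and 0 in autonomy, did not pass the filter on low counts and was not tested here.

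The G2, S-phase, histone and ribosomal protein lists passed camera as lower in DP autonomy, and each lost the call with an estimated correlation. Of 29 G2 and mitosis genes 0 rose, 10 fell and 19 did not pass, and adjusted over the list alone 25 fell (camera adjusted p = 4.16e-17, and adjusted p = 0.229 with an estimated correlation). Without turnover library RP1140B 5 fell. Bub1b fell from 248 to 76.3 CPM and Anln from 141 to 48.2 CPM. Of 28 S-phase genes 1 fell, Mcm6 (log2 −0.81), 3 without autonomy library RP1138, and 27 did not pass, with 6 falling adjusted over the list alone (camera adjusted p = 1.00e-05, and adjusted p = 0.347 with an estimated correlation). Of 21 histone genes 1 fell, H2afx (log2 −0.996), the same adjusted over the list alone (camera adjusted p = 1.76e-06, and adjusted p = 0.176 with an estimated correlation). Of 60 ribosomal protein genes 3 fell and 57 did not pass, with 1 rising and 11 falling adjusted over the list alone (camera adjusted p = 0.000189, and adjusted p = 0.557 with an estimated correlation); Rps4x fell by log2 −0.83 (SE 0.11). In the list 1 gene fell without each turnover library and without autonomy library RP1133, RP1135 or RP1136. Mcm6 and H2afx each lost the call in 6 of the 9 fits that left out a library, with adjusted p up to 0.0955 and 0.0808, without turnover library RP1140B.

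**Figure D2:**
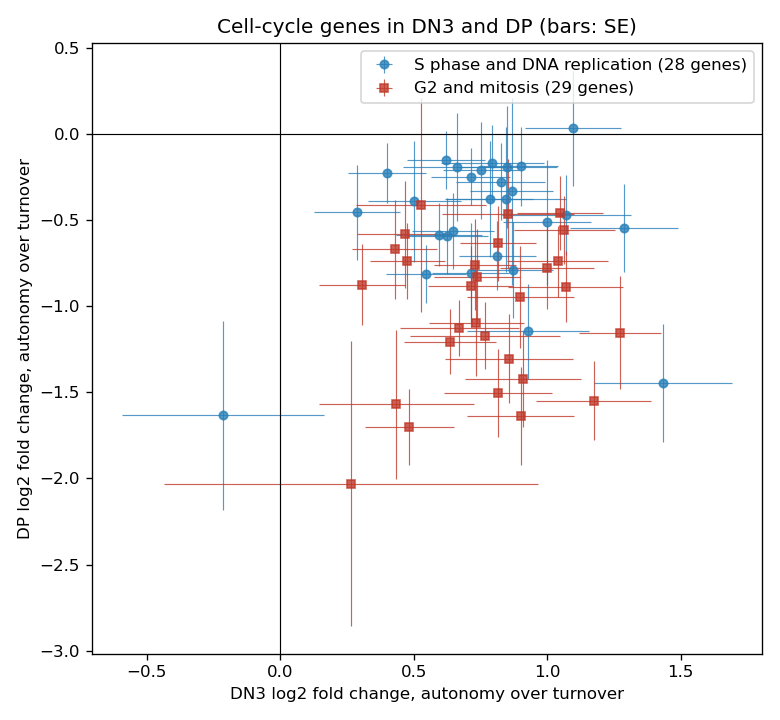
Log2 change, autonomy over turnover, of 28 S-phase and 29 G2 and mitosis genes, in DN3 cells on the horizontal axis and in DP cells on the vertical axis, with SE bars. The G2 genes have a median of 0.77 in DN3 and −0.89 in DP cells.

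Lists of genes induced by receptor signalling and interferon passed camera as higher in DP autonomy, as did macrophage and dendritic cell markers, and each lost the call with an estimated correlation. Of 16 pre-TCR and TCR signal-induced genes 3 rose and 13 did not pass, with 6 rising adjusted over the list alone (camera adjusted p = 0.000167, and adjusted p = 0.229 with an estimated correlation); Cd2 rose by log2 1.15 (SE 0.17). In the list 1 gene rose without each turnover library and without autonomy library RP1133 or RP1135. Of 7 Notch genes 1 rose, Dtx1, and adjusted over the list alone 3 rose (camera adjusted p = 0.000487, and adjusted p = 0.176 with an estimated correlation). Of 14 immediate early and heat shock genes 3 rose, with 7 adjusted over the list alone (camera adjusted p = 0.000167, and adjusted p = 0.176 with an estimated correlation); Dnaja1, a co-chaperone, rose by log2 0.81 (SE 0.13). In this list 1 rose without turnover library RP1140B or RP1141A. Of 22 positive selection genes 1 rose, Itm2a (log2 1.47), with 5 adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.229 with an estimated correlation); the list call was lost without autonomy library RP1137 (0.104), and without RP1138 4 genes rose. Of 28 interferon-stimulated genes 2 rose, Irf9 (from 39.7 to 119 CPM) and Trim30a (log2 1.32), and 12 without autonomy library RP1138, with 13 adjusted over the list alone (camera adjusted p = 3.48e-05, and adjusted p = 0.393 with an estimated correlation). Of 10 macrophage markers 1 rose, C1qc, with 4 adjusted over the list alone (camera adjusted p = 5.87e-05, and adjusted p = 0.229 with an estimated correlation); all 10 had positive log2 changes, with a median of 1.75, and Lyz2, chosen after its values were seen, went from 7.41 to 28.4 CPM (adjusted p = 0.256). Of 8 dendritic cell markers 0 passed by edgeR, 4 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom, with 3 rising adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.396 with an estimated correlation; 0.069 by camera without autonomy library RP1135); Cd74 went from 2.53 to 26.7 CPM. Irf9 and Itm2a lost the call in 6 of the 9 fits that left out a library and Trim30a in 8, with adjusted p up to 0.106 (Irf9, without turnover library RP1141A), 0.0808 and 0.0955 (without turnover library RP1140B).

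Of 35 oxidative phosphorylation genes 0 passed in DP cells by edgeR, over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom, at a median log2 change of 0.22 (camera adjusted p = 0.000422, and adjusted p = 0.393 with an estimated correlation). Of 13 mitochondrially encoded genes 4 rose, with 6 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00337, and adjusted p = 0.229 with an estimated correlation). Without turnover library RP1140A, RP1140B, RP1141A or RP1141B 2, 0, 0 and 1 mitochondrial genes rose, and without autonomy library RP1133 or RP1135 1 and 2. The following lists did not pass camera. Of 22 T-lineage identity genes 3 rose and 2 fell, with 8 and 5 adjusted over the list alone (0.191); Lat, the T-cell receptor adaptor, rose from 1845 to 3024 CPM (log2 0.71, SE 0.08). Of 18 double-positive stage genes 2 rose and 1 fell, with 3 and 3 adjusted over the list alone (0.845). Of 14 Rag recombination genes 1 fell, Dntt, with 5 rising and 1 falling adjusted over the list alone (0.195). Of 15 IL-7 receptor pathway genes 1 rose, with 4 adjusted over the list alone (0.188), and of 20 leukaemia genes 2 fell, with 2 rising and 5 falling adjusted over the list alone (0.182). Of 26 Myc targets 1 rose, with 2 rising and 2 falling adjusted over the list alone (0.414), and of 18 stress response genes 1 rose, with 2 adjusted over the list alone (0.263). Of 13 glucocorticoid-responsive genes 1 fell, with 3 adjusted over the list alone (0.65), and of 19 glycolysis genes 2 fell, with 4 adjusted over the list alone (0.0581); the glycolysis list passed without turnover library RP1141B (0.0407) or autonomy library RP1133 (0.0358) or RP1138 (0.033).

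In DP cells 0 genes passed, by edgeR over all genes, among 20 p53 targets (camera adjusted p = 0.65), 12 Bcl2 family genes (0.516), 21 cholesterol synthesis genes (0.106), 10 gamma-delta genes (0.827), 8 NK markers (0.191) and 5 thymic epithelial markers (0.516), and 0 adjusted over the list alone. At an unadjusted p under 0.05 the numbers, in that order, were 2, 2, 3, 3, 2 and 0; DESeq2 called 1 cholesterol, 1 gamma-delta and 1 NK gene and voom 0. Of 5 B-cell markers 1 fell, Ly6d (log2 −0.94), the same adjusted over the list alone (0.827); it lost the call in 6 of the 9 fits that left out a library, with adjusted p up to 0.0784, without turnover library RP1141A. Too few genes were expressed to test early progenitor genes (0 of 4 passed), fibroblast and endothelial (0 of 1), erythroid (0 of 2) or kidney tubule genes (0 of 2), and no mast cell gene was tested. The 13 lists that passed camera in DP cells all lost the call with an estimated correlation. The median, mean and test differed in sign for the double-positive stage, B-cell, NK and thymic epithelial lists.

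The difference of the autonomy effect between DP and DN3 cells was tested directly over 11521 genes. Anln had a difference of −2.72 on the log2 scale (SE 0.32), Bub1b −2.18 and Ccna2 −2.54. Of 29 G2 genes 24 had a lower effect in DP than in DN3 cells, 0 a higher effect and 5 did not pass, and 28 were lower adjusted over the list alone (median −1.80; camera adjusted p = 1.86e-30, and adjusted p = 0.0318 with an estimated correlation). Of 28 S-phase genes 17 were lower, with 27 adjusted over the list alone (median −1.19; camera adjusted p = 7.58e-20, and adjusted p = 0.0335 with an estimated correlation), and of 21 histone genes 5, with 10 adjusted over the list alone (camera adjusted p = 1.07e-09, and adjusted p = 0.0318 with an estimated correlation). Without DN3 library RP1140A, RP1141B or RP1134 or DP library RP1140A or RP1141A 3 histone genes were lower. Ccr9 fell in DN3 autonomy and stood at 2253 CPM in both DP groups (difference 4.74, SE 0.56, adjusted p = 0.000125), and Arsi rose in DN3 autonomy and stood at 45.5 and 44.5 CPM in DP (−4.09, SE 0.43, adjusted p = 7.03e-05). In all 633 genes passed, 332 with a higher and 301 with a lower effect in DP cells; without DN3 turnover library RP1141B 424 passed, 404 of them among the 633. With A and B libraries summed 145 passed, with a fixed replicate block 291, and with DESeq2 1037. Ccr9, Arsi, Anln, Bub1b and Ccna2, which the rule picks in the DN3 or DP comparison but not for the difference, were chosen here after their values were seen.

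The largest differences by the naming rule were often in genes with no reads in a group, for which the fitted values are no bounds. Casp1, an inflammatory protease, fell from 61.9 to 6.10 CPM in DN3 and went from 0.255 to 5.24 CPM in DP cells (difference 8.28, SE 1.97, adjusted p = 0.0172). Id1 rose from 0.373 to 19.1 CPM in DN3 and went from 5.68 to 3.41 CPM in DP cells (−6.36, SE 1.40, adjusted p = 0.011). Clec7a, a fungal glucan receptor of myeloid cells, went from 0.47 to 0 CPM in DN3 and from 0 to 10.5 CPM in DP; Clec12a, a myeloid lectin, from 69.2 to 14.1 and from 0 to 0.959 CPM; Ncf4, an oxidase subunit, from 13.4 to 1.51 and from 0 to 1.32 CPM. Kit went from 54.6 to 11.1 CPM in DN3 and from 9.97 to 0 CPM in DP, and Ttc8 from 11.2 to 3.17 and from 7.04 to 0 CPM. These 7 kept the call without each library, at sizes that moved. Casp1 was at 9.31 without DN3 autonomy library RP1135, 12.4 without DP turnover library RP1140A and 7.62 without RP1140B. Id1 was at −7.43 without DN3 turnover library RP1141B, Clec7a at 12.5 without DN3 turnover library RP1140A, and Ttc8 at −6.58 without DP turnover library RP1140B. Ncf4 was at 11.4 without DN3 autonomy library RP1135 and at 9.61 and 9.49 without DP autonomy libraries RP1136 and RP1137, and Clec12a at 8.23 without RP1136. Tifa lost it without DP autonomy library RP1136 (log2 difference 4.03), Rhov without DP turnover library RP1140B (−6.14), Adam19 without DP turnover library RP1141A (−6.48) and Ifi204 without DP turnover library RP1141B (adjusted p = 0.214), and Sytl4 in 13 of the 18 cases, with adjusted p between 0.0527 and 1.

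Other lists whose effects differed by camera did not hold with an estimated correlation. Higher in DP than in DN3 cells were the effects of positive selection genes (9 of 23 higher, with 11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00105, and adjusted p = 0.0727 with an estimated correlation), T-lineage genes (5 of 25, 9 adjusted over the list alone; 0.0156, and adjusted p = 0.35 with an estimated correlation) and interferon-stimulated genes (2 of 33, 3 adjusted over the list alone; 0.00856, and adjusted p = 0.605 with an estimated correlation). The interferon call was lost without DN3 autonomy library RP1138 (0.0627). With 1 library left out 5 interferon genes passed without DN3 library RP1135 and 4 without DP library RP1138. Of the T-lineage genes 3 passed without DN3 library RP1140A, RP1133, RP1137 or RP1138 or DP library RP1140B, RP1136 or RP1137. Macrophage markers (3 of 10, the same adjusted over the list alone; 0.000713, and adjusted p = 0.333 with an estimated correlation) and dendritic cell markers (0 of 9 by edgeR, with 6 at an unadjusted p under 0.05, 3 by DESeq2, 0 by voom and 4 adjusted over the list alone; 0.0108, and adjusted p = 0.35 with an estimated correlation) moved the same way as these lists. Without DP library RP1140A edgeR passed 3 dendritic markers. Without library RP1141A, RP1141B, RP1133 or RP1135 of either cell type or DN3 library RP1137 or RP1138 it passed 1 macrophage marker. Lower in DP were the effects of ribosomal protein genes (3 of 60, 6 adjusted over the list alone; 1.24e-07, and adjusted p = 0.494 with an estimated correlation), glycolysis genes (2 of 20, the same adjusted over the list alone; 0.0145, and adjusted p = 0.35 with an estimated correlation) and Myc targets (2 of 26, the same adjusted over the list alone; 0.0212, and adjusted p = 0.37 with an estimated correlation). The Myc call was lost without DN3 turnover library RP1140B (0.0649), DN3 autonomy library RP1138 (0.0608) or DP autonomy library RP1136 (0.0508). Without DN3 library RP1140B, RP1141A or RP1135 6, 5 and 5 ribosomal protein genes were lower. In all 11 lists passed camera.

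Of 9896 genes tested in both cell types, 19 were higher in autonomy in both, where independent lists would share 5.69 (Fisher's exact test, adjusted p = 9.91e-06). They included Ctse (log2 3.08 in DN3 and 5.04 in DP), Cd2 (3.06 and 1.15), Igf2bp3 (1.66 and 1.90), Phlda1 (3.26 and 2.04) and Dtx1 (1.30 and 2.99). Lower in both were 13 genes, against 7.08 (adjusted p = 0.0378), among them Dntt (−0.96 and −0.39), Myb (−1.13 and −0.61) and Pdk1 (−1.10 and −0.75). Another 13 were higher in DN3 and lower in DP, against 5.83 (adjusted p = 0.0147): Kif15, Anln, Cdc20, Plk1, Ccna2, Racgap1, Mki67, Bub1, Lmnb1, Prc1, Ncaph, Mcm6 and Pold1. Another 4 were lower in DN3 and higher in DP, Cd3g, Traf3ip3, Rsrp1 and BC025920, against 6.92 (adjusted p = 0.319). These Fisher tests count genes as independent units, which they are not, so their p-values do not measure a spread between samples. Of these 49 genes 7 stayed in their set without each library, namely Ctse, Cd2, Dtx1, Igf2bp3, 3830403N18Rik, Anln and Rsrp1. In DP cells Phlda1, Dntt, Myb and Pdk1 lost the call without some libraries, with adjusted p up to 0.12, 0.0532, 0.0957 and 0.135. Without turnover library RP1140B all 4 did. The 4 sets, in the order given, numbered 11, 8, 7 and 3 without DN3 turnover library RP1140A. They numbered 13, 9, 7 and 2 without DP turnover library RP1140A, 5, 2, 2 and 1 without RP1140B, 10, 2, 10 and 1 without RP1141A and 7, 2, 8 and 1 without RP1141B. They numbered 10, 4, 6 and 2 without DP autonomy library RP1133, 8, 5, 13 and 6 without RP1135 and 19, 10, 25 and 9 without RP1138. The last set numbered 8 without DN3 turnover library RP1140B. Genes of these sets that the naming rule did not pick were chosen after their values were seen. Across genes, which are not independent replicates, the log2 changes of both cell types had a Pearson r of 0.152 and a Spearman rho of 0.088. With libraries of the same condition regrouped by identifier, r ran from −0.0584 to 0.0921. Leaving out 1 library moved r between 0.074, without DN3 turnover library RP1140B, where rho was −0.03, and 0.20, without DN3 turnover library RP1141B.

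DP and DN3 cells were also compared within each condition, a known developmental step. In turnover, Il7r, the IL-7 receptor, was at 145 CPM in DN3 and 0 in DP cells, at least 553-fold lower, and Il2ra, the CD25 chain that marks DN3 cells, fell from 417 ± 96.8 to 7.73 ± 6.22 CPM. Rag1, of the receptor recombinase, rose from 110 ± 51.6 to 728 ± 57.0 CPM (log2 2.73, SE 0.32, adjusted p = 2.81e-06), and Cd4 and Cd8a rose by log2 4.51 and 4.46. Myc fell by log2 −4.02 (SE 0.23), Notch1 by −3.08, Ptcra, the pre-TCR alpha chain, by −2.62, Hes1, a Notch target, by −7.80, Bcl2 by −2.49 and Cdkn1a by −5.29. Without DN3 turnover library RP1141B Cd4 and Cd8a were at log2 9.39 and 8.67. Without DP turnover library RP1141B Hes1 had no reads left in DP cells, without RP1140B it was at −7.15, and without RP1141A Cdkn1a was at −5.91. Spib was at least 32.8-fold lower. In all, 4021 of 11521 genes passed, 1820 higher and 2201 lower in DP cells, and 2170 with A and B libraries summed. Themis, which sets T-cell receptor signal strength, rose by log2 1.86, Ets2 by 2.79 and Tcf7 by 1.06. Of the named genes that passed, 16 of 18 kept the call without each library; Kit (log2 −2.45, adjusted p = 0.0263) and Ly6d (−0.86, 0.0373) lost it in 3 and 7 of the 8 cases, with adjusted p up to 0.0645 (without DN3 turnover library RP1140B) and 0.152 (without DN3 turnover library RP1141B). Dntt, Cd3e and Bcl11b did not pass.

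In autonomy 5643 genes passed, 2736 higher and 2907 lower in DP cells, and all 20 named genes that passed kept the call without each library. Ccr9 rose from 10.7 to 2253 CPM (log2 7.74, SE 0.47, adjusted p = 2.78e-10), Cd4 from 3.78 to 805 CPM, and Cd8a and Rag1 by log2 5.18 and 2.96. Kit was at least 30.8-fold lower in DP cells. Mki67 fell by log2 −0.90 (SE 0.26) from DN3 to DP in autonomy, where in turnover it rose by 1.25 (SE 0.29). Of 29 G2 genes 11 rose and 0 fell from DN3 to DP in turnover, with 13 rising adjusted over the list alone (camera adjusted p = 4.12e-05, and adjusted p = 0.327 with an estimated correlation), while in autonomy 0 rose and 23 fell, the same adjusted over the list alone (camera adjusted p = 1.33e-06, and adjusted p = 0.242 with an estimated correlation). Dntt (log2 0.49), Bcl11b (1.11) and Cd247, the zeta chain of the receptor (1.88), rose in autonomy, and Il7r (−5.93, and −6.57 without DP autonomy library RP1136), Il2ra (−3.71) and Myc (−4.61) fell.

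Double-positive stage genes were higher and Myc targets lower in DP than in DN3 cells in both conditions. Of 18 double-positive stage genes 15 rose and 1 fell in turnover, with 16 and 1 adjusted over the list alone (camera adjusted p = 7.78e-10, and adjusted p = 0.107 with an estimated correlation), and 17 rose and 0 fell in autonomy, with 17 and 1 adjusted over the list alone (7.54e-10, and adjusted p = 0.0897 with an estimated correlation). Of 26 Myc targets 24 fell in turnover and 25 in autonomy, with 25 and 26 adjusted over the list alone (8.50e-16 and 6.76e-15, and adjusted p = 0.0078 and 0.0117 with an estimated correlation). Of 15 gamma-delta genes 2 rose and 10 fell in turnover (4.12e-05, and adjusted p = 0.0175 with an estimated correlation) and 4 rose and 11 fell in autonomy (0.00375, and adjusted p = 0.0897 with an estimated correlation). Of 20 stress response genes 1 rose and 13 fell in turnover (0.000516, and adjusted p = 0.0175 with an estimated correlation) and 2 rose and 12 fell in autonomy (0.00193, and adjusted p = 0.0544 with an estimated correlation). S-phase genes fell in 22 of 28 cases in turnover and in all 28 in autonomy (1.47e-06 and 2.11e-15, and adjusted p = 0.239 and 0.0788 with an estimated correlation). Of 25 T-lineage genes 13 rose and 5 fell in autonomy (0.00829, and adjusted p = 0.177 with an estimated correlation), with a median of 0.67 and a mean of −0.03 on the log2 scale. Macrophage markers rose in 8 of 10 cases in autonomy (0.00193, and adjusted p = 0.206 with an estimated correlation) and in 1 of 10 in turnover. In each condition 16 lists passed camera, and with an estimated correlation 3 did in turnover and 1 in autonomy.

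The authors' deposited DESeq2 tables called more genes than the edgeR test at the same threshold of 0.05. In DN3 cells they listed 2377 genes, 1106 higher and 1271 lower in autonomy, and held 1594 of the 1602 genes called by edgeR. At 0.01 they listed 1369, 1318 of them among the 1602 that edgeR called at 0.05. In DP cells they listed 854 genes, 438 higher and 416 lower, and held all 178 called by edgeR; at 0.01 they listed 394. The signs of the log2 changes matched for 99.95% of the DN3 genes compared and for 100% in DP. The deposited mean of normalized counts in the DP table was recovered within 1% from the 9 DP libraries for 100% of 11675 genes. In the DN3 table it was recovered for 0.00894% of 11188 genes, with a median ratio of 1.25. No set of DN3 libraries that left out 1 or 2 did better than 2.05%, and scaling over all 18 libraries gave 2.32%. Around its median ratio, the set of all 9 DN3 libraries held 65.6% of the genes within 1%. Sets that left out 1 library held 13.51% to 29.25% around theirs. Most genes thus differed by a shared factor, but the input to that table was not worked out.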

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

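Among the tests below, the tests for RNA from DP cells in library RP1141B, on its own markers and on G2 genes, and the test for a strain or donor variant were chosen only after the result was seen; the others were set before it.

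DN3 turnover library RP1141B stood apart with 135 CPM of Cd4 and 385.3 of Cd8a. Over 32 genes abundant in DP turnover and low in the other 3 DN3 turnover libraries, it held a median of 19.44% of the DP level, with quartiles of 15.1% and 27.6%, where the 5 DN3 autonomy libraries, not used to choose the genes, held 0.1685% to 2.047%, the highest in RP1133. The tables argue against a mislabelled sample, since its mean correlation was higher with the other DN3 turnover libraries than with DP turnover by 0.1157. RNA from DP cells that passed the DN3 sort is a candidate explanation that goes with the median over the 32 genes. Cd4, at 17.1%, and Cd8a, at 17.2% of their DP levels, flagged the library and so do not test it, and Cd8b1 was at 31.2%. Ccr9, at 8.14%, is also expressed by DN3 turnover cells, and no biological explanation was tested, as the design gives none for a single library.

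Of 29 G2 and mitosis genes 20 rose in DN3 autonomy and 10 fell in DP autonomy, with a median difference between the effects of −1.796 on the log2 scale. With every library thinned to 5032000 counts the median was −1.811 and 24 genes passed. Thinning keeps the expected share of each gene in its library, so the median had little room to move. It therefore does not decide whether library depth plays a part. The tables argue against 2 other technical explanations, GC content or gene length bias and RNA from DP cells in RP1141B. Of 10000 lists matched on GC content, gene length and expression, 0 had a median difference as low, the lowest being −0.5551. Without RP1141B the G2 genes had a median of 0.6293 from DN3 to DP in turnover, with quartiles of 0.4236 and 1.059. By this, DP RNA in that library would raise these genes in turnover and shrink their DN3 rise. Leaving RP1141B out did not enlarge the rise, so that reasoning was not borne out. The median DN3 log2 change of the list was 0.7226 without that library and 0.7661 with it, and 16 genes rose against 20. The rise thus remained without RP1141B, which is what argues against DP RNA as its source. A hypothesis that these tests leave open, found and tested on the same data, is that more DN3 and fewer DP cells were in cycle in autonomy, which DNA content measured in each sorted population would test. Other differences between the grafts were not tested.

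H2-Q, H2-T and Ifi200 genes were among the largest DN3 changes in both directions, with 10 of the 19 tested passing. Of 14 members tested in both cell types 11, or 78.57%, had the same sign in both, short of the 80% set for a strain or donor variant and above the 50% that would argue against one, while H2-Q2, the member with the lowest adjusted p in DN3, went from log2 2.672 there to 0.04576 in DP (adjusted p of the difference 7.03e-05), which does not go with a variant acting alike in both. Ifi211, Ifi204, H2-Q5, H2-Q6 and H2-Q7, which passed in DN3, were not tested in DP cells and are not among the 14. The members that passed in DN3 and were tested in DP, H2-Q1, H2-Q2, H2-T3, H2-T10 and Ifi208, had the same sign in both. Those with opposite signs, Ifi209, H2-T22 and Ifi213, did not pass in DN3, so the share rests partly on genes with no clear change. Of 121 genes changed by at least 3 on the log2 scale, 29.8% had another within 1 Mb, above the 95th percentile of random sets, 27.3%. The 121 include clustered members of these families, so this share partly restates the pattern. Summed over 11 H2-Q and H2-T genes the log2 ratio was 0.5352, between the bounds of 0.3 and 0.6 set for reads shared between paralogs, with 329 ± 36 CPM in turnover and 477 ± 102 in autonomy. A strain or donor variant, reads shared between paralogs and a change in expression cannot be told apart here, because neither value reached its bound and the labels give no strain.

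A single library stood apart from the rest of its group in 44 of 427 group values, where chance alone marks about 1 in 20 groups, or 21.35 values. In DN3 autonomy, library RP1135 had Atp8b4 at 54.94 CPM, Cdkn1a at 38.75, Epcam at 82.17, H2-Q6 at 2.881, Lat2 at 5.465, Lyz2 at 11.53, Nfe2 at 16.1, Nkg7 at 65.28 and Tcf4 at 66.27. Library RP1134 had Anln at 186.6, H2-T3 at 49.21 and Mki67 at 914, RP1133 had Cd4 at 7.969 and Rbm44 at 4.958, and RP1137 had H2-Q1 at 21.25 CPM. In DN3 turnover, besides Cd4 and Cd8a, library RP1141B had Ass1 at 43.13, Btg2 at 220.3, Ccnd3 at 436.3, Cd2 at 87.0 and Cd52 at 86.18 CPM, and RP1140B had Hmmr at 84.87, Myb at 766.3, Necab1 at 2.729, Tcf4 at 72.62 and Tcf7 at 996.8. In DP autonomy, RP1133 had C1qc at 32.77 and Car2 at 21.41, RP1136 mt-Co3 at 214.4, Nop56 at 464.9 and Tbc1d19 at 12.79, RP1138 Myc at 31.45, RP1137 Tcf7 at 1534 and RP1135 Tyrobp at 56.32 CPM. RP1137 also had the largest total of its group, 20076446 counts. In DP turnover, RP1140A had Cd4 at 646.6, Cd74 at 6.122 and Epcam at 13.56, RP1140B Cd8a at 2328, Mycn at 6.436 and Tyrobp at 2.818, RP1141B Hes1 at 3.456 and RP1141A Rpl10 at 488.5 CPM.

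Of the genes that the naming rule picked, 58 had autonomy effects that differed between DP and DN3 cells by the edgeR test of the difference, given here on the log2 scale as DP minus DN3. The rule picked 12 of these because they passed this same test, and others for a large change in a single cell type, so the number is no independent result. Lower in DP, among genes of the cell cycle and chromatin, were Anln (−2.715), Bub1b (−2.182), Ccna2 (−2.539), Ccnd3 (−1.203), Ccne1 (−2.873), Ccne2 (−1.828), Ezh2 (−0.8793), Gtse1 (−1.761), H2afx (−1.346), H2afz (−1.25), Hist1h2ae (−1.732), Hmgb2 (−1.095), Hmmr (−2.424), Mcm6 (−1.356), Mki67 (−2.153), Ncaph (−2.155), Nup205 (−2.117) and Tmpo (−1.673). Lower too were Arsi (−4.095), Gzma (−1.485), Id1 (−6.357), Ifi204 (−6.053), Mthfd2 (−1.479), Rpl10 (−1.021), Rps2 (−0.9762), Tbc1d19 (−2.702), Tpi1 (−1.926), Uqcrfs1 (−0.7148) and Vars (−1.877). Higher in DP were Btg2 (1.436), Casp1 (8.282), Ccr9 (4.736), Cd1d1 (1.646), Cd3g (1.565), Cd52 (3.642), Egr1 (2.32), Irf9 (2.133), Lat (1.14), Lyz2 (4.572), mt-Cytb (0.8185), Pecam1 (0.9284), Pik3ip1 (2.871), Scin (6.68), Tmsb10 (1.685) and Trp53inp1 (1.503). With no reads in a group, so that the fitted values are no bounds, were Adam19 (−10.74), Kit (−7.64), Rhov (−10.92), Tbx21 (−11.68) and Ttc8 (−7.613), and 5830411N06Rik (10.27), Clec12a (9.005), Clec7a (15.54), Il7r (7.86), Ncf4 (10.2), Sytl4 (8.783), Tifa (9.649) and Wscd1 (6.524).

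The effects of 11 lists differed between the cell types by camera, and 8 of them lost the call with an estimated correlation, all but S phase, G2 and mitosis, and histones. The median differences on the log2 scale were −1.188 for S phase, −1.796 for G2 and mitosis, −1.517 for histones, −0.2463 for Myc targets, −0.4102 for glycolysis and −0.442 for ribosomal proteins. They were 0.4531 for T-lineage genes, 0.8737 for positive selection, 0.9568 for interferon-stimulated genes, 2.015 for macrophage markers and 3.632 for dendritic cell markers. With groups at 0 set to the floor of 3 counts per library the dendritic median was 2.25, and the other 10 were the same.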

How the results depend on the processing

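Leaving out each library for the correlation and the overlap of DN3 and DP effects was chosen only after the data were seen, and the cause of each change below was not tested, except that a stricter threshold and a test against 1.5-fold pass fewer genes by construction. Direction and side of the threshold held for 2613 named-gene values under other settings, 379 lost the call, 24 gained it and 12 changed direction; for lists the numbers were 730, 70, 26 and 9. With 1 library left out they were 1975, 338, 9 and 21 for genes and 1525, 12, 34 and 35 for lists. In DN3 cells 2869 genes passed with voom and quality weights, 524 at a threshold of 0.01, 328 against 1.5-fold, 507 with A and B libraries summed and 1006 in a fit of all 18, and 811 to 1784 with 1 library left out. In DP cells it was 736 with DESeq2, 272 with voom, 22 at 0.01, 9 against 1.5-fold, 16 with A and B summed, 279 in a fit of all 18, and 33 to 252 with 1 library left out. The difference gave 1037 with DESeq2, 192 at 0.01, 170 against 1.5-fold, 145 with A and B summed and 291 with a fixed replicate block; DP against DN3 in turnover gave 2592 at 0.01, 2230 against 1.5-fold and 2170 with A and B summed. With the replicate block DP against DN3 gave 3604 genes in turnover and 4822 in autonomy. Deviations of libraries with the same identifier correlated at 0.00118 to 0.0521, all positive. With different identifiers they correlated at −0.0632 to 0.0559. The main fits did not pair the samples, but such small values do not show that the samples are unpaired. With an estimated correlation 0, 0, 3, 3 and 1 lists passed. The correlation of effects was 0.1038 over genes at 10 CPM or more and 0.07403 to 0.1997 with 1 library left out. These log2 changes, none past the threshold before, turned direction: Ass1 in DN3 was 0.01085 with RLE, 0.01533 without mitochondrial and ribosomal protein genes in the scaling, 0.01593 without a filter, 0.01039 with a 1 CPM filter, 0.01077 with DESeq2, 0.03477 with voom and 0.008521 in a fit of all 18; Cd4 and Cd8a in DN3 were 0.7376 and 2.469 with voom; Pecam1 and Cd4 in DP were −0.0003792 and −0.02815 with A and B summed; Cd3e from DN3 to DP in turnover was −0.03423 with voom. List tests that turned direction had adjusted p = 0.7086 (cholesterol in DN3), 0.2665 (immediate early genes in turnover), 0.08535 (IL-7 pathway), 0.2703 (leukaemia) and 0.08761 (NK, these in autonomy) with fry, and 0.9538 (B cell in DP), 0.828 (NK in DP), 0.7525 (NK, difference) and 0.9504 (NK, autonomy) with A and B summed. With 1 library left out, log2 changes that turned ranged, in DN3, from −0.2082 to 0.1233 for Ass1, −0.3412 to 0.02573 for Il2ra, −0.3299 to 0.04843 for Il7r, −0.307 to 0.2579 for Rag1, −3.664 to 1.652 for Cd4 and −1.196 to 3.371 for Cd8a, in DP from −0.01853 to 0.2694 for Pecam1, −0.02232 to 0.8794 for Cubn and −0.06518 to 0.08608 for Cd4, and in turnover from −0.0006672 to 0.1952 for Cd3e. Adjusted p of lists that turned ranged, in DN3, over 0.5532 to 0.996 (pre-TCR), 0.04258 to 0.7286 (double-positive stage), 0.08934 to 0.9852 (interferon), 0.6474 to 0.9356 (cholesterol) and 0.3286 to 0.9405 (mitochondrial); in DP, over 0.6824 to 0.9735 (double-positive stage), 0.441 to 0.9574 (gamma-delta), 0.4315 to 0.9506 (p53) and 0.05591 to 0.9045 (NK); in the difference, over 0.4958 to 0.956 (Rag), 0.01702 to 0.4176 (double-positive stage) and 0.3979 to 0.9916 (NK); in turnover, over 0.6235 to 0.9395 (leukaemia) and 0.2906 to 0.8507 (NK); in autonomy, over 0.7829 to 0.9998 (leukaemia and NK) and 0.3172 to 0.9785 (interferon). Upper-quartile scaling moved the DN3 median of all genes from −0.0459 to −0.111 and the share of calls that were higher from 43.9% to 35.7%. On simulated counts a 2-fold change was recovered for 62% of the changed genes in DN3 and 41% in DP, so many changes of that size can be missed.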

Other observations

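Of the tests in this part, leaving out each library for the segments was chosen only after the data were seen. Transcripts of T-cell receptor gene segments, which were left out of the gene naming, changed in several classes in DN3 autonomy. Of the beta segments 9 of 13 Trbj fell, at a median log2 change of −2.17, while of 21 Trbv segments 1 rose and 0 fell. Of 2 beta constant and 2 beta diversity segments 1 each fell. Of the gamma segments 3 of 4 joining ones fell (median −1.26), 2 of 7 variable ones rose, and of 4 constant ones 1 rose and 2 fell. The delta joining and constant segments tested fell, at −2.49 and −1.49, as did 1 of 4 delta variable segments. With each library left out in turn 8 or 9 Trbj segments fell. Of the Trbv segments 3 rose without turnover library RP1141B or autonomy library RP1135, 0 without RP1140A, RP1140B, RP1141A or RP1134, and 2 fell without RP1138. Of 8 Trav segments 3 fell, at a median of −1.38, but 1 without each turnover library and without autonomy library RP1133 or RP1137. In DP autonomy 2 of 13 Trbj segments fell, but 1 without autonomy library RP1138 and 0 without any other library. Trac, the alpha constant segment, rose by log2 0.59 and lost the call without each turnover library and without autonomy library RP1133, RP1135 or RP1136, with adjusted p up to 0.101 (without RP1141A). The gene 3830403N18Rik, on the X chromosome and chosen after its values were seen, had no reads in either autonomy group, at least 48.2-fold lower in DN3 and at least 74.2-fold lower in DP.

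Other splits of the same libraries into groups of the same sizes tested whether chance gives as large a result. The splits take libraries that share a number and differ in the letter as separate samples, which the labels do not state. For the difference and for DP against DN3 they also did not keep libraries with the same identifier together. On these conditions chance is unlikely to give the number of genes called in any comparison. The real split alone, 1 of 100, reached 1602 genes in DN3 (highest other 1108) and 178 in DP (63). The 1108 came from the real split with only autonomy library RP1135 moved to the turnover side, and the 63 likewise with only RP1138 moved. The real split alone also reached 633 in the difference (182) and 5643 in DP against DN3 in autonomy (124). In turnover it alone, 1 of 35, reached 4021 (40). For the lists in DP 4 of 100 splits, the real one among them, reached 13 (highest other 14). The grouping with 14 lists was the real split with only autonomy library RP1136 moved to the turnover side. It keeps most of the real contrast and so is a weak guide to chance, which is not excluded. In DP against DN3 in turnover the real split alone, 1 of 35, reached 16 lists (15). With an estimated correlation 0 of the 13 and 3 of the 16 passed. Nor can chance be excluded for the 9 lists in DN3, reached by 24 of 100 splits (15). The same holds for the 11 lists of the difference, by 11 of 100 (14), and the 16 lists of DP against DN3 in autonomy, by 11 of 100 (20).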
